A study of Mus with 16 samples.

How the data were processed

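The series holds 16 libraries of total RNA, ribodepleted and sequenced in bulk, from mouse epiblast stem cells. Epiblast stem cells are pluripotent cells that correspond to the epiblast of the embryo after implantation. The cells are F1 hybrids of the laboratory strain C57BL/6J with 4 wild-derived inbred strains. The 4 crosses are CastB6, MolfB6, PwkB6 and SpretB6, with 4 libraries each, and each library carries a number in its title. The groups were taken from the titles. The labels do not say that libraries of a cross came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be partly technical.

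Each library has 1 table of transcript abundances, and per the file headers its columns hold the transcript length, the effective length, TPM and estimated counts. The deposited estimated counts are numbers of reads per transcript that need not be whole, because reads that match several transcripts are divided among them. The deposited TPM values scale the abundances of the same transcript set to a fixed sum per library. The submitters' processing notes name Salmon, DESeq2 and the genome build mm10. Their versions, the transcript set and its release, and any bias or strand setting are not given in the sources used here. How the non-C57BL/6J allele was matched is not stated either. A read with a variant of the wild-derived parent can be matched less well, and that loss was not measured here. Allele-level data were not analysed here.

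Each table lists 116747 transcripts by their Ensembl transcript ID. The table of mouse genes of the assembly GRCm38.p6 used here carries no Ensembl IDs, so 0 IDs could be matched, which says nothing about whether that annotation holds these transcripts. The files do not pair the transcripts with gene names. The planned sums per gene could therefore not be made, and every test was run per transcript. Differences in gene expression and in the use of a gene's transcripts are not separated. The planned tests of gene lists, the values of sex-linked genes, the 6 genes to be given in every case, the alternative with protein-coding transcripts and the alternative without the X and Y chromosomes were not run for the same reason. The lengths come from the files.

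Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Transcripts were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 56721. Library sizes were scaled by TMM. A quasi-likelihood fit over all 16 libraries gave the F tests, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A transcript is called changed when it passes that threshold. Each cross was compared with the mean of the log levels of the other 3 crosses, each pair of crosses was compared, and 1 joint test asked whether the 4 crosses differ. A log2 fold change against the other 3 crosses exceeds the ratio of mean TPM where those 3 differ among themselves. Standard errors were computed from the log2 fold change and the F statistic. The tables carry no bootstrap estimates, so the uncertainty of dividing reads among similar transcripts is in none of the tests. Log2 CPM for correlations and principal components used a prior count of 2.

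On simulated counts for the same 56721 transcripts, the comparison of SpretB6 with the other 3 crosses recovered 3% of transcripts changed 1.5-fold, 19.4% of those changed 2-fold and 48.5% of those changed 4-fold. In that simulation 3 of 50 calls were false. The simulated comparison of CastB6 with MolfB6 recovered 1.5%, 4.5% and 28.8% at the same folds, with 0 false among 23 calls. In each simulation only 67, 67 and 66 transcripts were changed at these folds, whereas the real SpretB6 comparison called 4029. The adjusted threshold depends on the share of true changes, so these rates do not carry over directly to the real tests. In the simulated setting the tests missed many changes of these sizes.

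Library totals ran from 42596559 to 72364991 estimated counts. Where a transcript had 0 reads in a library, a count of 3 was taken as the upper limit, which is 0.0415 to 0.0704 CPM. For a fold against a cross with 0 reads in all 4 libraries, 3 reads over the whole cross were used, and the fold is given as a lower bound. These limits cover counting error only. Where a transcript shares reads with others, 0 reads can come from how the reads were divided, and the true fold may be smaller. A transcript whose estimates lie within 0.001 of a whole number in all 16 libraries was taken to share no reads with another transcript. This holds for 12665 listed and 1335 tested transcripts. A transcript with reads in few libraries has fewer chances of a fractional estimate, so a whole estimate does not prove that no reads are shared. The fragment length correction of a library is the median difference between length and effective length over transcripts longer than 2000 bases.

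The rule for named transcripts was fixed before the data were examined. For each cross it takes the largest rises and falls among called transcripts with a mean log2 CPM of at least 1 in which all 4 libraries of the cross lie above, or below, all 12 others in log2 CPM. The counts of transcripts outside the range of the 12 others use the same measure. The fixed rule also kept only protein-coding and long non-coding RNA where an annotation gives the type, and left out predicted or clone names. Neither condition could be applied without annotation, so transcripts of such kinds may be among those named. Because no gene names were at hand, 2 rises and 2 falls per cross are given, and none for the pairs and the joint test. That limit was set after the data were examined. The comparisons, tests and most alternatives were also fixed before. The test over partitions of the libraries, the counts of transcripts present or absent in 1 or 2 crosses and the axis within crosses were chosen after the data were examined.

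The settings fixed beforehand for comparison were DESeq2 size factors in place of TMM, no filter on low counts, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0 and limma 3.58.1 voom with quality weights as other tests, transcript length offsets, the library number as a replicate block, only the 8 libraries of 2 crosses in a fit of that pair, a prior count of 0.5, and each library left out in turn. The fragment length correction as a covariate, other read limits for presence and absence, and Pearson in place of Spearman correlation were added after the data were examined. Correlations and exact tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

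Libraries of a cross were compared with each other for duplicates. Over the 24 pairs, chi-square per degree of freedom lay between 19.1 and 163, far above sampling noise, so all libraries were counted singly.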

Results

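Bulk RNA-seq was made from epiblast stem cells of 4 F1 crosses so that allelic mapping could be compared between bulk and droplet single-cell data. The deposited tables give transcript totals without alleles, and they were used here to compare the crosses with each other. As strain names are commonly used, CAST comes from Mus musculus castaneus, PWK from Mus musculus musculus, MOLF from Mus musculus molossinus and SPRET from the separate species Mus spretus. Every cross shares the C57BL/6J genome as its other parent.

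The 16 libraries held 61172849 ± 8970308 estimated counts (SD, n = 16), from 42596559 in PwkB6 1 to 72364991 in SpretB6 3. Between 61229 and 67901 transcripts had reads in a library. Of the 116747 transcripts listed, 22262 had no reads in any library. The 100 most abundant transcripts took 20.1% ± 1.34 of the estimated counts (SD, n = 16). Mean totals were 63540992 ± 5734574 in CastB6, 63497628 ± 3193159 in MolfB6, 57957601 ± 12782556 in PwkB6 and 59695175 ± 12824900 in SpretB6 (SD, n = 4 each).

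Libraries resembled their own cross more than other crosses. The mean Spearman correlation of log2 CPM across transcripts was 0.8956 over the 24 pairs of libraries within a cross (SD 0.0175) and 0.8661 over the 96 pairs from different crosses (SD 0.015). Of 2627625 ways to divide the 16 libraries into 4 sets of 4, 1 gave a mean within sets as high as the real crosses, namely the real division (one-sided exact permutation p = 3.81e-07, the smallest this design can give). The next highest division reached 0.8946. The closest library belonged to the same cross for 15 of 16 libraries. The exception was PwkB6 5, whose closest library was MolfB6 6 with a correlation of 0.9052. Between crosses, the mean correlation was highest for MolfB6 with PwkB6 (0.8779) and CastB6 with MolfB6 (0.8765), and lowest for PwkB6 with SpretB6 (0.8562) and CastB6 with SpretB6 (0.8585). The order of the highest pairs turned with Pearson correlation, where CastB6 with MolfB6 came first.

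The first principal component held 14.8% of the variance and separated SpretB6 from the other 3 crosses, with 99.3% of its own variance between crosses. The second held 11.5% and ordered CastB6, MolfB6 and PwkB6, with 86.8% of its variance between crosses. The third held 10.3%, of which 3.5% lay between crosses. Over all tested transcripts, 33.6% of the variance of log2 CPM lay between crosses. The median transcript had 30.5% there, against 20% by chance. When the transcripts were divided into 4 equal classes by mean level, that median was 38.7% in the highest class and 24.3% in the lowest.

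**Figure D1:**
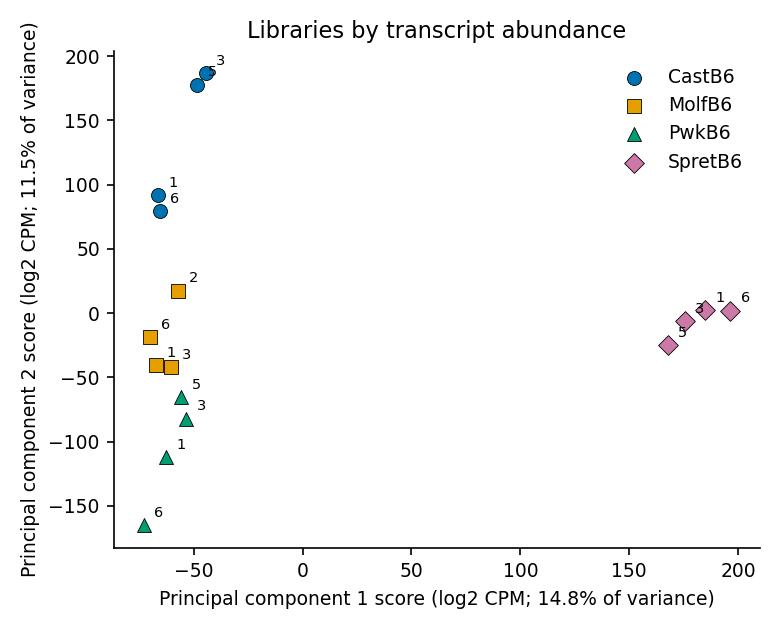
Scores of the 16 libraries on principal components 1 (x axis) and 2 (y axis) of log2 CPM over 56721 transcripts; each point is 1 library, with its number, and colour and shape give the cross. The 4 SpretB6 libraries lie between 168 and 197 on component 1 and the 12 others between -73.0 and -44.6.

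Libraries of a cross lay apart by different amounts. The median over transcripts of the SD of log2 CPM was 0.3622 in SpretB6, 0.4006 in MolfB6, 0.4507 in CastB6 and 0.5175 in PwkB6 (n = 4 each). In the highest class by level the medians were 0.1539, 0.1959, 0.2155 and 0.3277. No test of these differences was run. With 1 library left out, the PwkB6 median over all tested transcripts lay between 0.4263 (without PwkB6 6) and 0.5189 (without PwkB6 1). The CastB6 median lay between 0.3939 and 0.4297, so the place of PwkB6 above CastB6 depends on PwkB6 6.

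Abundance differed among the 4 crosses for 5519 of the 56721 tested transcripts, or 9.73% (joint edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted). Of these, 2647 were called only in a pair with SpretB6 and 158 in no single pair. Among the 1335 tested transcripts taken to share no reads with another, 216 were called, or 16.2%. That set favours transcripts with reads in few libraries, so its share is not directly comparable with the one over all. DESeq2 called 11022 transcripts and limma voom 9306.

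In SpretB6, 4029 transcripts differed from the other 3 crosses, 2453 higher and 1576 lower. The median log2 fold change was 1.23 among the rises and -1.02 among the falls. Rises of over 2-fold numbered 1467 and falls of over 2-fold 804. In 2166 of the called transcripts, the 4 SpretB6 libraries all lay outside the range of the 12 others. In the lowest class by level, 674 were called and 83.2% of them were higher, while in the highest class 1475 were called and 54.6% were higher. Rises also led in the lowest class in CastB6 (58.8%), MolfB6 (62.4%) and PwkB6 (66.8%). The classes were cut on the mean over all 16 libraries. A transcript with reads in a single cross has a low mean, so the lowest class favours rises by design. Among the 1335 transcripts taken to share no reads, 145 were called (10.9%), against 7.01% of the others. Transcripts with reads in few libraries more easily have whole estimates, so these shares are not compared like for like. The transcript ENSMUST00000222811.2, of 859 bases, reached 1246 ± 66.3 TPM in SpretB6 (SD, n = 4) and 0 to 4.03 TPM in the 12 other libraries. Its log2 fold change was 10.82 ± 0.54 (SE; edgeR adjusted p = 3.35e-09), and 11.834 under limma voom. ENSMUST00000117531.2 stood at 799 ± 40.3 TPM in SpretB6 and 393 ± 24.5 TPM in CastB6, and at 0.179 ± 0.125 in MolfB6 and 0.156 ± 0.073 in PwkB6 (SD, n = 4 each). Its log2 fold change against the other 3 crosses was 8.51 ± 0.18 (SE; edgeR adjusted p = 1.99e-13). ENSMUST00000118791.2 had 0 reads in all 4 SpretB6 libraries and 306 ± 98.3 TPM in the others (SD, n = 12), at least 13000-fold lower than the mean of the other crosses. ENSMUST00000117447.2 had 13 reads over the 4 SpretB6 libraries, or 0.271 ± 0.274 TPM (SD, n = 4), against 823 ± 89.3 TPM (SD, n = 12), a log2 fold change of -11.57 ± 0.44 (SE; edgeR adjusted p = 1.78e-10). SpretB6 3 held 8 of these reads, and without it the value was -12.362. All 4 transcripts share reads with others, so their estimates depend on how those reads were divided. DESeq2 called 6566 transcripts and limma voom 7691.

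In CastB6, 2563 transcripts differed from the other 3 crosses, 1609 higher and 954 lower. Rises were mostly small, with a median log2 fold change of 0.78, and 633 of them passed 2-fold. Falls were larger, with a median of -1.18, and 567 of them passed 2-fold. In the highest class by level, 1196 were called and 76.4% of these were higher. The size of this lead depends on the setting. Over all CastB6 calls 62.78% were higher, against 54.71% with a filter of 5 CPM and 56.59% without CastB6 1. It was 56.88% under DESeq2 and 66.82% under limma voom. The 4 CastB6 libraries lay outside the range of the 12 others in 1052 called transcripts. Both named rises were shared with SpretB6. ENSMUST00000120762.2 stood at 1054 ± 42.9 TPM in CastB6 and 415 ± 7.12 in SpretB6, and at 17.9 ± 1.02 in MolfB6 and 15.3 ± 1.83 in PwkB6 (SD, n = 4 each). Its log2 fold change was 4.59 ± 0.085 (SE; edgeR adjusted p = 4.6e-13). ENSMUST00000187178.2 stood at 97.7 ± 10.7 TPM in CastB6 and 83.2 ± 10.9 in SpretB6, and at 0.951 ± 0.236 in MolfB6 and 0.869 ± 0.606 in PwkB6 (SD, n = 4 each), with a log2 fold change of 4.73 ± 0.26 (SE; edgeR adjusted p = 3.45e-08). The CastB6 and SpretB6 libraries overlapped in TPM here and were apart only in log2 CPM. ENSMUST00000212102.2 had 0 reads in all 4 CastB6 libraries and 514 to 2478 TPM in the 12 others, at least 16400-fold lower than the mean of the other crosses. ENSMUST00000081204.6 also had 0 reads there, against 25.7 to 108.5 TPM elsewhere, at least 5310-fold lower. All 4 transcripts share reads with others, so these lower bounds do not cover how the reads were divided. DESeq2 called 5520 transcripts and limma voom 4180, and 1327 were called without CastB6 5.

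In MolfB6, 1458 transcripts differed from the other 3 crosses, 776 higher and 682 lower. The median log2 fold change was 1.26 among the rises and -1.09 among the falls, and 479 rises and 371 falls passed 2-fold. The 4 MolfB6 libraries lay outside the range of the 12 others in 471 called transcripts. ENSMUST00000121545.2 stood at 1689 ± 34.4 TPM in MolfB6 and 1139 ± 94.4 in PwkB6, and at 15.6 ± 3.52 in CastB6 and 8.34 ± 0.693 in SpretB6 (SD, n = 4 each). Its log2 fold change was 5.03 ± 0.13 (SE; edgeR adjusted p = 5.69e-11). ENSMUST00000121654.2 stood at 91.5 ± 3.68 TPM in MolfB6, 49.9 ± 4.38 in SpretB6 and 38.1 ± 1.34 in CastB6 (SD, n = 4 each), and had 0 reads in all 4 PwkB6 libraries. Its fitted log2 fold change against the other 3 crosses, 5.53 ± 0.10 (SE; edgeR adjusted p = 1.98e-10), rests on that absence in PwkB6 and depends on the prior count, and limma voom gave 4.771. ENSMUST00000109467.4 had 0 reads in all 4 MolfB6 libraries and 38.1 ± 9.78 TPM in the others (SD, n = 12), at least 2020-fold lower. ENSMUST00000123179.2 had 0 reads there and 25.7 ± 6.96 TPM in the others (SD, n = 12), at least 1120-fold lower. All 4 transcripts share reads with others, so these lower bounds do not cover how the reads were divided. DESeq2 called 3400 transcripts and limma voom 3531, while 848 were called without MolfB6 1 and 869 without MolfB6 6. The slight majority of rises, 53.22%, did not hold under DESeq2, where 45.38% of the calls were higher, or without MolfB6 2, where 49.28% were.

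In PwkB6, 1724 transcripts differed from the other 3 crosses, 849 higher and 875 lower. The median log2 fold change was 1.32 among the rises and -0.90 among the falls, and 568 rises and 400 falls passed 2-fold. In the highest class by level, 750 were called and 36.0% were higher. The 4 PwkB6 libraries lay outside the range of the 12 others in 458 called transcripts. ENSMUST00000119608.2 stood at 517 ± 28.5 TPM in PwkB6 and 180 ± 31.4 in SpretB6, and at 0.199 ± 0.0281 in CastB6 and 0.272 ± 0.159 in MolfB6 (SD, n = 4 each). Its log2 fold change was 7.71 ± 0.20 (SE; edgeR adjusted p = 2.32e-11). ENSMUST00000105742.8 stood at 39.4 ± 12 TPM in PwkB6 and 16.6 ± 4.59 in CastB6 (SD, n = 4 each), and 6 of the 8 MolfB6 and SpretB6 libraries had 0 reads. Its fitted log2 fold change of 5.81 ± 0.96 (SE; edgeR adjusted p = 0.00318) depends on the 2 libraries with reads, as it was 8.966 without MolfB6 6 and 7.423 without SpretB6 1, and DESeq2 gave it no adjusted p. ENSMUST00000183478.2 had 0 reads in all 4 PwkB6 libraries and 595 ± 181 TPM in the others (SD, n = 12), at least 14400-fold lower. ENSMUST00000121654.2, named above as a MolfB6 rise, was at least 2400-fold lower in PwkB6 than the mean of the other crosses. All 4 transcripts share reads with others, so these lower bounds do not cover how the reads were divided. DESeq2 called 4708 transcripts, while 975 were called without PwkB6 1 and 3044 without PwkB6 5. Which direction held the majority depended on the setting, with 49.25% of the calls higher here, 42.71% under DESeq2, 58.57% under limma voom, 54.70% with a filter of 5 CPM and 57.40% without CastB6 1.

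**Figure D2:**
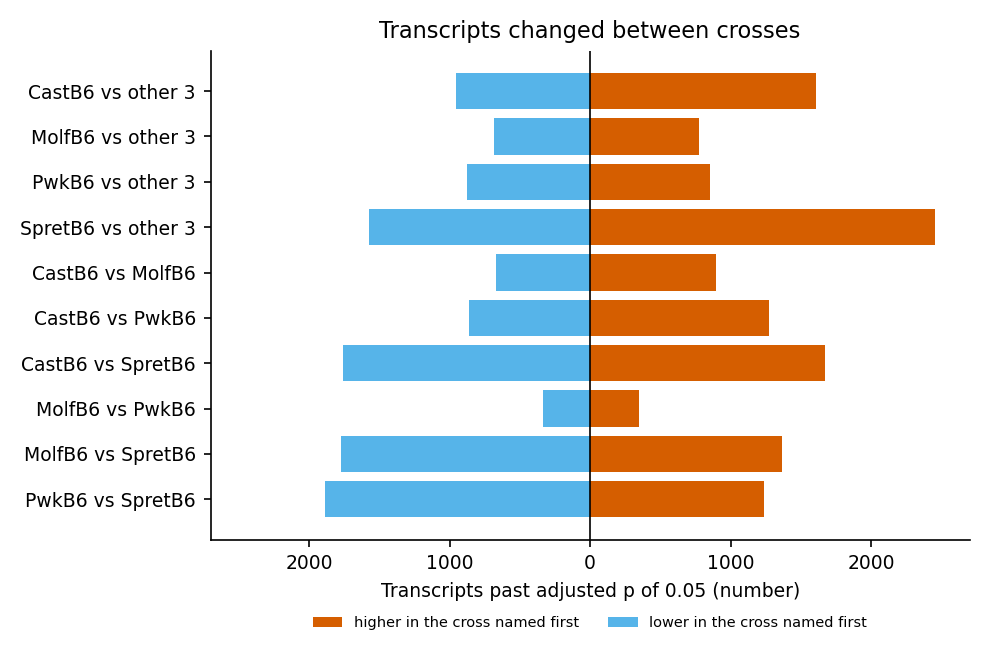
Number of transcripts past a Benjamini-Hochberg adjusted p of 0.05 in each of 10 comparisons (x axis); bars to the right count transcripts higher in the cross named first and bars to the left those lower. The 4 top bars compare a cross with the other 3, with 4029 calls for SpretB6, and the shortest bar, MolfB6 against PwkB6, stands for 682.

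The pair MolfB6 and PwkB6 differed in 682 transcripts, 349 higher and 333 lower in MolfB6. CastB6 and MolfB6 differed in 1564, 894 of them higher in CastB6, and CastB6 and PwkB6 in 2134, with 1273 higher in CastB6. The pairs with SpretB6 gave 3430 with CastB6, 3137 with MolfB6 and 3121 with PwkB6, more than the other pairs here, but not under DESeq2 or without PwkB6 5, where CastB6 against PwkB6 (5711 and 3380) passed MolfB6 against SpretB6 (5636 and 3248). In those 3 pairs the transcripts higher in SpretB6 numbered 1756, 1772 and 1883. Among falls in MolfB6 against PwkB6, 77.5% passed 2-fold, and among falls in CastB6 against SpretB6 72.8% did. DESeq2 called 3817 transcripts for CastB6 against MolfB6, 5711 for CastB6 against PwkB6, 6265 for CastB6 against SpretB6, 2501 for MolfB6 against PwkB6, 5636 for MolfB6 against SpretB6 and 6017 for PwkB6 against SpretB6. Limma voom called 3237 for CastB6 against MolfB6, and 5945, 7133 and 4809 for SpretB6 with CastB6, MolfB6 and PwkB6. With only the 2 crosses in the fit, the counts were lower, 658 for CastB6 against PwkB6, 372 for MolfB6 against PwkB6 and 1980 for PwkB6 against SpretB6, and with no filter CastB6 against PwkB6 gave 1403. CastB6 against MolfB6 fell to 871 without MolfB6 1, 926 without CastB6 5, 994 without MolfB6 6 and 1006 without MolfB6 3. CastB6 against PwkB6 gave 1060 without CastB6 5, 1251 without PwkB6 1, 1340 without CastB6 3 and 3380 without PwkB6 5, and MolfB6 against PwkB6 gave 437 without MolfB6 1. The share higher in CastB6 against PwkB6, 59.65%, was 48.73% without CastB6 1 and 49.34% with a filter of 5 CPM, and the near even splits of CastB6 against SpretB6 (48.80% higher in CastB6, 51.75% under DESeq2) and MolfB6 against PwkB6 (51.17% higher in MolfB6, 41.67% with only these 2 crosses in the fit) also turned.

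Some transcripts were present in 1 cross and absent in the other 3. With at least 10 reads in all 4 libraries of a cross and at most 3 in each of the 12 others, SpretB6 had 140 such transcripts, PwkB6 13, CastB6 12 and MolfB6 4. With the limits reversed, 25 transcripts were absent in CastB6 alone, 13 in SpretB6, 11 in MolfB6 and 8 in PwkB6. Of those present, 11 in SpretB6, 2 in PwkB6, 2 in CastB6 and 1 in MolfB6 had whole estimates in all 16 libraries. Of those absent, 1 in SpretB6 and 0 in CastB6, MolfB6 and PwkB6 did. The rest share reads with other transcripts, so these states can come from how reads were divided. Among the 1816 sets of 4 libraries that are not a cross, the highest counts were 5 present and 4 absent. The 140 SpretB6 transcripts had a median of 66.0 reads per library there and a median length of 645 bases, against 1838 for all tested transcripts. Their number was 63 with at least 50 reads for presence and 61 with 0 reads for absence. Short length was not particular to SpretB6. Transcripts present or absent in 1 cross only had median lengths of 997 bases in CastB6, 756 in MolfB6 and 768 in PwkB6. Without MolfB6 3, 18 were absent in MolfB6 alone, and without PwkB6 5, 14 were absent in PwkB6 alone.

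**Figure D3:**
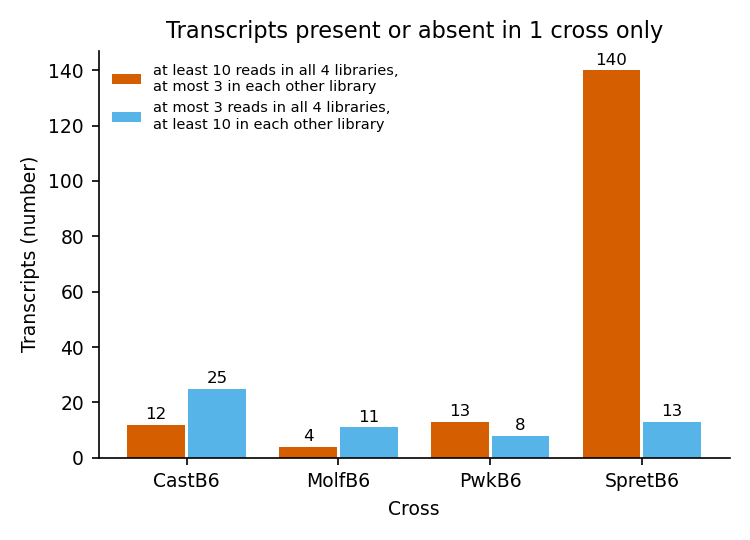
Number of transcripts (y axis) present in all 4 libraries of 1 cross and absent in the 12 others (orange), or the reverse (blue), for each cross (x axis). SpretB6 has 140 present and 13 absent, and no other bar is above 25.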

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

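An outlying library was sought in 85 groups of 4 libraries, over library totals, transcripts with reads, correlations, component scores and the TPM of named transcripts. In 3 groups 1 library stood far from the other 3. A rate of 1 in 20 would give about 4.2 such groups. The groups are not independent and some hold tied values, so this is not an exact chance count. Where 3 libraries tie at 0, as for ENSMUST00000105742.8 below, any value above 0 in the other library is flagged. No explanation was tested for the 3 groups.

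ENSMUST00000081204.6, absent in CastB6, stood at 108.5 TPM in PwkB6 6 and at 38.6 to 48.6 in the other 3 PwkB6 libraries. ENSMUST00000105742.8, a rise of PwkB6, stood at 2.388 TPM in MolfB6 6 and at 0 in the other 3 MolfB6 libraries. The same transcript stood at 0.1062 TPM (13 reads) in SpretB6 1 and at 0 in the other 3 SpretB6 libraries.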

How the results depend on the processing

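Under the alternatives run, 383 values of the named transcripts stayed past the threshold in the same direction, and 1 is missing, as DESeq2 gave no adjusted p for ENSMUST00000105742.8 in PwkB6. The 11 counts of changed transcripts stayed within 1.5 times under DESeq2 size factors, the filter of 5 CPM in 4 libraries, transcript length offsets and the fragment length covariate, which was chosen after seeing the data. Under the filter of 5 CPM, which left 18781 transcripts, the called transcripts were only partly the same. In PwkB6 1035 of its 2000 calls were shared with the main 1724, and in SpretB6 2097 of 2828 with the main 4029. With transcript length offsets, 1716 of 1728 PwkB6 calls were shared. Other settings moved counts, and the cause was not tested. DESeq2 in place of edgeR called 5520 transcripts in CastB6, 3400 in MolfB6, 4708 in PwkB6 and 6566 in SpretB6 against the other 3 crosses, and 11022 in the joint test. For the pairs it called 3817 (CastB6, MolfB6), 5711 (CastB6, PwkB6), 6265 (CastB6, SpretB6), 2501 (MolfB6, PwkB6), 5636 (MolfB6, SpretB6) and 6017 (PwkB6, SpretB6). Limma voom with quality weights called 4180 in CastB6, 3531 in MolfB6, 7691 in SpretB6, 9306 in the joint test, 3237 (CastB6, MolfB6), 5945 (CastB6, SpretB6), 7133 (MolfB6, SpretB6) and 4809 (PwkB6, SpretB6). With no filter, CastB6 against PwkB6 gave 1403. With only 2 crosses in the fit, which leaves fewer libraries to estimate the spread, it gave 658, MolfB6 against PwkB6 372 and PwkB6 against SpretB6 1980.

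The library numbers were not taken to pair libraries across crosses. The deviations of same-numbered libraries correlated by 0.001 on average over 21 pairs, 1 of them over 0.1, and 1 of 16 libraries correlated best with its own number. With the number as a replicate block, counts fell to 640 in MolfB6, 1070 in PwkB6, 3581 in the joint test, 797 (CastB6, MolfB6), 1360 (CastB6, PwkB6), 304 (MolfB6, PwkB6) and 1717 (MolfB6, SpretB6), and the other 4 counts stayed within 1.5 times. In MolfB6 48.91% of these calls were higher, against 53.22% without the block.

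Leaving out each library in turn gave 1327 (without CastB6 5) to 3181 calls in CastB6, 848 (without MolfB6 1) to 1857 in MolfB6, 975 (without PwkB6 1) to 3044 (without PwkB6 5) in PwkB6 and 2688 to 4678 in SpretB6. The ranges were 871 (without MolfB6 1) to 2123 for CastB6 against MolfB6, 1060 (without CastB6 5) to 3380 (without PwkB6 5) for CastB6 against PwkB6, and 437 (without MolfB6 1) to 990 for MolfB6 against PwkB6. The spread within a cross, over 3 libraries, ranged from 0.3939 to 0.4297 in CastB6, 0.3114 to 0.3959 in MolfB6, 0.4263 to 0.5189 in PwkB6 and 0.2926 to 0.3552 in SpretB6.

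The read limits for presence and absence were changed after seeing the data. The 140 SpretB6 transcripts became 63 at 50 reads for presence and 61 at 0 reads for absence, and lay between 140 and 151 without any 1 library. Of the 8 counts present or absent in 1 cross, 7 moved by over 1.5 times under either limit. The 22 transcripts present in 2 crosses became 8 and 12 under these limits, and 22 to 28 without any 1 library. Alternatives that need gene annotation were not run.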

Other observations

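The tests in this part were chosen after the data were examined, except the other groupings of libraries. The test of the axis against library totals was set after both were seen, but before their correlation was computed. The test of shared ancestry was set after the values of the named transcripts were known, but before its own count was. Where a first test was followed by a second, both are given.

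Several transcripts were shared by 2 crosses. With the same read limits, 22 transcripts were present in all 8 libraries of 2 crosses and absent in the other 8. CastB6 with SpretB6 had 9, CastB6 with MolfB6 4, and MolfB6 with PwkB6, MolfB6 with SpretB6 and PwkB6 with SpretB6 3 each. CastB6 with PwkB6 had 0. Among the 12864 sets of 8 libraries that are not 2 whole crosses, the highest count was 2. A hypothesis was that shared ancestry of the MOLF and PWK parents may give this pair more than its share among CastB6, MolfB6 and PwkB6. It held 3 of 7, or 42.9%, against 33.33% by chance (two-sided exact binomial p = 0.693, 95% interval 9.90% to 81.6%). The test counted shared presence only, and 7 transcripts cannot decide the hypothesis. Transcripts are also not independent. Read as shared absence, the same counts gave 9 for MolfB6 with PwkB6, 3 for CastB6 with MolfB6 and 3 for CastB6 with PwkB6. Shared absence was not tested.

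The 140 transcripts present in SpretB6 alone are the first pattern weighed, and of all 1820 sets of 4 libraries 1 had as many, the SpretB6 set itself, so chance sets do not account for it. Reads divided differently among similar transcripts could give such states, and a first test, over all 4 crosses, asked whether on or off states are rarer among transcripts that share no reads; it gave the opposite, 17 of 1335 against 209 of 55386 (odds ratio 3.405, 95% interval 1.94 to 5.61, two-sided Fisher's exact p = 2.99e-05), which its stated bound read as evidence against divided reads. After that outcome the bound was judged wrong from the design, because a transcript with reads in 4 libraries has fewer chances of a fractional estimate than one with reads in 16, although the difference was also there among transcripts below a mean log2 CPM of -2 (17 of 439 against 157 of 12596; above it, 0 of 896 against 52 of 42790). A second test, chosen then, compared the 140 with 1400 transcripts matched on SpretB6 reads and found 7.86% against 4.57% with whole estimates in the SpretB6 libraries (odds ratio 1.78, 95% interval 0.825 to 3.51, two-sided Fisher's exact p = 0.097). The 2 sets were not matched on length, with medians of 645 bases for the 140 and 1777 for the matched transcripts. Divided reads therefore stay open, as does sequence of the SPRET genome that matches a listed transcript, a biological explanation that was not tested.

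The second pattern is an axis of variation within crosses, the first principal component after each cross mean was removed, which held 15.7% of the variance within crosses against 10.95% for the next and 8.33% if spread evenly. Its score correlated within crosses with the fragment length correction (Pearson r = 0.688, exact permutation p = 0.01, adjusted p = 0.0168 over 3 measures; Spearman rho = 0.69, exact permutation p = 0.0125; r = 0.6 without MolfB6 6 and PwkB6 3) and with library totals (r = -0.566, exact permutation p = 0.0112, adjusted p = 0.0168; rho = -0.606, exact permutation p = 0.0103; r = -0.6 without PwkB6 1 and SpretB6 6), but not detectably with the share of the top 100 transcripts (r = 0.09, exact permutation p = 0.773; rho = 0.133, exact permutation p = 0.67; r = 0.318 without PwkB6 5 and PwkB6 6). The test of fragment length also required transcript loadings to follow length, and this failed (rho = 0.003), which argues against fragment length acting through transcript length and leaves its correlation unexplained. Thinning every library to the smallest total, added after the correlation with totals was seen, gave the same axis (r = 1.0), which argues against counting noise but not against the correlation with totals. Fragment length and totals correlated with each other within crosses (r = -0.62, exact permutation p = 0.0299), so their parts were not separated, and differences in library preparation or in the state of the cells stay open.

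The third pattern is deep falls in SpretB6, since poor matching of reads from the SPRET allele could remove at most that allele's part. If both alleles contributed equally, a called fall of a transcript that shares no reads should stop near a log2 fold change of -1. Of 20 such falls with a mean log2 CPM of at least 1, 4 lay below -1 by more than 2 standard errors, or 20% (exact 95% interval 5.70% to 43.7%), above the 5% set as the bound, which the test as written read as evidence against loss of one allele's reads. After that outcome the bound was set aside, because it assumes equal alleles, which these tables do not show, so loss of one allele's reads stays open. By the same count, CastB6 had 0 of 15, MolfB6 0 of 2 and PwkB6 2 of 6, too few falls to compare the crosses. Over all called falls at this level, which include transcripts that share reads, deep falls were not particular to SpretB6. There they were 144 of 1024 in SpretB6 (14.1%), 79 of 500 in CastB6 (15.8%), 74 of 425 in MolfB6 (17.4%) and 75 of 618 in PwkB6 (12.1%).

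Other groupings of the same libraries gave far fewer calls in each comparison. A grouping that mixes crosses puts differences between crosses into the spread within groups, which can lower its calls. These counts therefore show a division by cross, but not whether it comes from the crosses or from cultures or preparation shared within a cross. Over 100 groupings of the 16 libraries, 1 was as large as the real one in each case, the real one itself. The highest other was 61 against 5519 in the joint test, 30 against 2563 in CastB6, 186 against 1458 in MolfB6, 7 against 1724 in PwkB6 and 8 against 4029 in SpretB6. For the pairs, over 35 splits of 8 libraries, again 1 was as large. The highest other was 13 against 1564 (CastB6, MolfB6), 42 against 2134 (CastB6, PwkB6), 3 against 3430 (CastB6, SpretB6), 3 against 682 (MolfB6, PwkB6), 3 against 3137 (MolfB6, SpretB6) and 3 against 3121 (PwkB6, SpretB6).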
